A study of Sus scrofa with 15 samples.

How the data were processed

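Expression was measured in backfat of 15 castrated male Iberian pigs, 7 on a control diet and 8 on a high-oleic diet, with 1 Affymetrix porcine array per animal. Per the labels' protocols, RNA was isolated with the RiboPure kit and biotinylated cRNA was prepared by the standard Affymetrix protocol. Feed was given so that both diets supplied equal energy and protein, with a larger quantity of the less energy-dense control feed. Diet group, animal number and live weight came from the labels.

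The authors deposited 1 table of log2 values per probe set. Per the submitters' processing notes, GCOS and GCRMA were used, and their versions, roles and settings are not given in the sources used here. The log2 scale and the lack of centring were read from the deposited values, which lay between 1.49 and 14.36. The table held 3272 probe sets. In all of them the 3rd largest deviation from the row median was 1.5-fold or more, the smallest being 0.59 on the log2 scale. Such a filter does not use the diet labels, and it was found from the values, as no source used here states it. Adjusted p-values therefore refer to these variable probe sets. Arrays correlated with each other between 0.762 and 0.958, and no 2 were identical.

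A table pairing probe sets with gene symbols was used for names. Of 3255 tested probe sets, 1455 had 1 symbol, 27 had several and 1773 had none, and 1260 genes were named. Probe sets with several symbols were not named. Older list symbols were matched through synonyms in a RefSeq gene table of assembly Sscrofa11.1, used for names alone. The 17 control probe sets of the manufacturer were left out of tests, and 7 of them, for Bacillus subtilis transcripts added to the RNA, gave a signal for spiked transcripts.

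The diet effect was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as high-oleic minus control, with no further normalization or filter. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, on the probe set with the highest mean per gene, for the 14 of 29 lists with 5 or more measured genes. A list score is the mean over members of the log2 value minus the member's mean over the 15 arrays. Live weight was compared by an exact permutation test over 6435 splits, and its slope was fitted in limma at fixed diet. Correlations across 10 or more animals used 100000 permutations and those across fewer used all orders. Figures were drawn with matplotlib 3.10.9.

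The rule for naming genes and the panel were fixed before the data were examined. The rule took the 12 per direction with the largest difference among those past the threshold, filled up to 12 by the smallest unadjusted p, with 1 probe set per gene. To these came 4 members of each called list in its direction, a panel of 20 genes and the 3 smallest p per direction for live weight, of which 1 is not reported here. As none passed, all named by the first part are described as not passing.

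The model was tested on simulated data with 200 changed probe sets among 3255, with log2 sizes of 1 and 2. It recovered 47% and 95% of them, with 3 false calls among 145. Simulated errors were independent between probe sets, which need not hold for the real arrays. The alternatives tried were a filter on dim probe sets, quantile normalization, median centring, leaving out each animal, live weight as a covariate, a window of live weight, the animal number as a block, other variance models, array weights, a floor, means over probe sets, an exact test, other thresholds and other list tests. Genes of lists too small to test were picked after their values were seen. Chosen after seeing the data were also the spiked signal as a covariate, leaving out animals with outlying arrays, keeping the control probe sets and a permutation test of list scores.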

Results

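Backfat, the subcutaneous fat over the back, was profiled in 15 castrated male Iberian pigs, a local breed with heavy fat deposition. There were 7 animals on a control diet and 8 on a high-oleic diet, whose name refers to oleic acid, the main monounsaturated fatty acid of pig fat. The labels give the tissue as the inner layer of the fat. Treatment started at 28 kg live weight and ended at slaughter at about 110 kg. One array was hybridised per animal, so the animal was the replicate. The table held 3272 probe sets as log2 signals, and 3255 were tested after 17 control probe sets were left out. Array medians lay between 6.38 and 6.67, and the number of arrays limits the precision. Every probe set of the table had at least 3 of the 15 arrays 1.5-fold or more away from its own median, so genes that varied less were not analysed here. The comparison of diets asks how oleic acid supplementation bears on fat tissue expression.

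The smallest p-values between diets were those of RXRG, CKB and PTGDS, but no single gene passed the test. RXRG, a retinoid X receptor that pairs with other nuclear receptors, had a log2 signal of 7.64 ± 0.34 (SD, n = 8) on the high-oleic diet. On the control diet it was 6.48 ± 0.52 (SD, n = 7), a difference of 1.17 with a standard error of 0.25. CKB, the brain-type creatine kinase, stood at 10.27 ± 0.92 on the high-oleic diet and 11.91 ± 0.53 on the control diet, a difference of -1.64 with a standard error of 0.36. PTGDS, which makes prostaglandin D from its precursor, stood at 10.95 ± 0.63 and 12.31 ± 0.68, a difference of -1.36 with a standard error of 0.32. In limma with Benjamini-Hochberg adjustment, the adjusted p was 0.315 for RXRG and CKB and 0.445 for PTGDS.

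Across the 3255 probe sets, limma placed 0 at an adjusted p under 0.05 and 0 under 0.10. At an unadjusted p under 0.05 there were 128, of which 66 were higher and 62 lower on the high-oleic diet, where 162.8 would be expected by chance. The exact permutation test over all 6435 splits also gave 0 after adjustment and 136 before it. The 95% interval of the difference lay within 2-fold in either direction for 74.4% of the probe sets. In simulated data with 200 of 3255 probe sets changed and independent errors, the test found 47.0% of those changed by 1 log2 unit and 95% of those changed by 2. Where fewer probe sets change the adjustment is stricter, so these shares need not hold for the real data.

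The 12 genes with higher signal on the high-oleic diet and the smallest p had varied functions, and none passed the adjusted test. UCP3, a mitochondrial uncoupling protein, was higher by 0.79 (95% interval 0.27 to 1.30), and its other probe set by 0.77. FBP2, the muscle form of fructose-bisphosphatase, was higher by 0.58, and all 8 high-oleic animals lay above all 7 control animals. HSD3B1, a steroid dehydrogenase, was higher by 1.33 on one probe set and 0.78 on another. BID, a mediator of apoptosis, was higher by 0.92, and the neuroendocrine chaperone SCG5 by 1.28. The phosphodiesterases PDE6C and PDE9A were higher by 0.90 and 0.72. The remaining 5 were LRRC8A at 0.88, CLSTN3 at 0.79, PLPP2 at 0.76, MYO5B at 0.89 and RXRG, given above. With live weight in the fit HSD3B1 was 0.75, BID 0.50 and MYO5B 0.38. Adjusted p was 0.999 for each of these genes other than RXRG.

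Among the genes with lower signal on the high-oleic diet, PTGS2, the inducible cyclooxygenase, differed by -0.90 (95% interval -1.46 to -0.34). CAP2, an actin-binding protein, differed by -0.95, and the nuclear receptor coactivator NCOA2 by -0.68. The fructose transporter SLC2A5 differed by -0.84, the phosphodiesterase PDE4B by -0.70 and the early response gene IER3 by -1.003. NUF2 of the kinetochore differed by -0.64, RND3 by -0.93 and PDLIM3 by -0.997. ACTG2, the smooth muscle gamma actin, differed by -1.85 on one probe set and by -0.16 on another. Without control animal 6 the former was -1.19. RND3 also had a second probe set, at -0.19. With live weight in the fit SLC2A5 was -0.45, PDE4B -0.46, RND3 -0.47 and PDLIM3 -0.65. In animals of 109.5 to 118 kg NCOA2 was -0.36. Adjusted p was 0.999 for each gene of this paragraph.

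**Figure D1:**
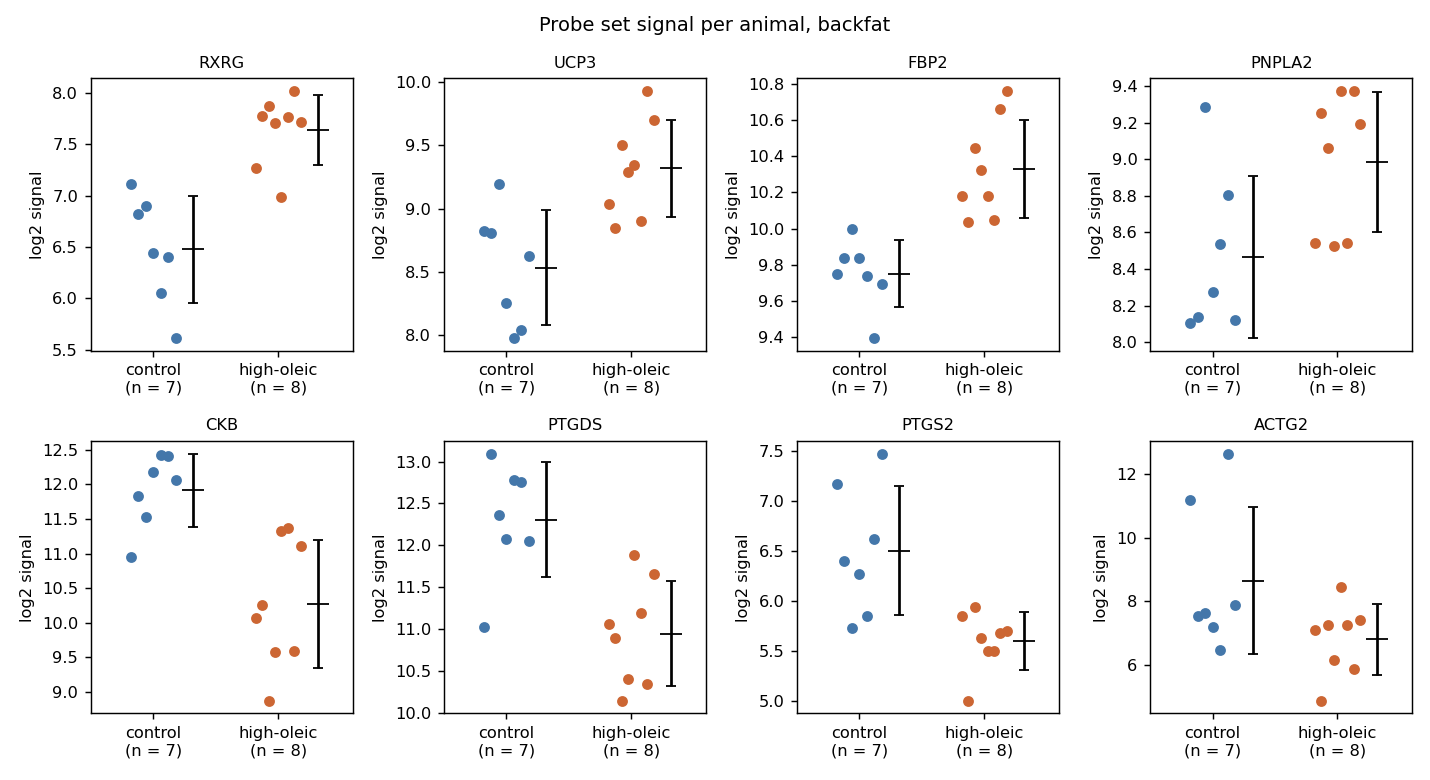
Log2 signal of 8 genes in backfat, with 1 point per animal (control, n = 7, and high-oleic, n = 8) and the group mean with SD beside the points. The vertical axes are log2 signal and differ between panels; RXRG, UCP3, FBP2 and PNPLA2 had higher means on the high-oleic diet and CKB, PTGDS, PTGS2 and ACTG2 lower ones, none past the adjusted threshold.

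Of a panel of 20 genes of fat metabolism chosen before the data were examined, 5 were measured and 15 were not analysed here. FASN, the fatty acid synthase, differed by 0.02 (95% interval -0.58 to 0.63), and ACACA, the acetyl-CoA carboxylase that supplies it, by -0.09 (95% interval -0.85 to 0.67). The signs of both turned when single animals were left out, and with live weight in the fit FASN was 0.49 and ACACA 0.70. PNPLA2, the adipose triglyceride lipase, was higher on the high-oleic diet by 0.52 (95% interval 0.00 to 1.03). CPT1A, which carries fatty acids into mitochondria, was higher by 0.54 (95% interval -0.06 to 1.14), or 0.33 without control animal 5 and 0.14 with live weight in the fit, and LEP, which encodes leptin, by 0.61 (95% interval -0.03 to 1.26). With live weight in the fit LEP was 0.98. None of the 5 passed the test, with an adjusted p of 0.999 for each.

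Gene lists fixed in advance gave 2 calls of 14 tested, and both were lost when the correlation between genes was estimated. Of the 20 smooth muscle and pericyte genes in the list 10 were measured. Of these 10, 9 had lower signal on the high-oleic diet, with a median difference of -0.47 and 0 members past the test. The camera adjusted p was 0.00238 at a preset correlation of 0.01, and adjusted p = 0.502 with an estimated correlation. ACTA2, the smooth muscle alpha actin, differed by -0.67, the tropomyosin TPM2 by -0.64 and DES, which encodes desmin, by -0.63. Without control animal 1 these were -0.45, -0.42 and -0.31. A second probe set of TPM2, not used for the list, differed by -0.24. The animal scores of this list differed by -0.43 (95% interval -1.002 to 0.15), with a two-sided exact permutation p of 0.154, and by -0.24 without control animal 1 and -0.27 without control animal 6. Scores of 1.33 and 1.16 in control animals 1 and 6 stood above the 13 other animals. The remaining control animals, numbers 2, 3, 4, 5 and 7, scored -0.22, -0.24, 0.02, -0.45 and -0.01. The high-oleic mean was -0.20 with a range of -0.51 to 0.22, and these control animals lay within that range. The lower mean therefore rested largely on control animals 1 and 6, and leaving out both was not tested. Without control animal 1 the camera adjusted p was 0.0549 and the median difference -0.23.

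All 6 measured targets of the peroxisome proliferator-activated receptors and peroxisomal genes had higher signal on the high-oleic diet, with a median difference of 0.38. The list was written with 29 genes, so these 6 do not stand for the whole pathway. The camera adjusted p was 0.0178, and adjusted p = 0.410 with an estimated correlation. PDK4, a kinase that restrains glucose oxidation, was higher by 0.81, ANGPTL4, an inhibitor of lipoprotein lipase, by 0.54 and UCP2 by 0.31, with UCP3 as above. Without control animal 5 PDK4 was 0.29 and ANGPTL4 0.30. With live weight in the fit PDK4 was -0.36 and ANGPTL4 0.06, and UCP2 was -0.21 in animals of 109.5 to 118 kg. For ANGPTL4 and UCP3 the list test used the brighter of the probe sets, at 0.45 and 0.77. Adjusted over the list alone, 1 member passed in the fit with 1 probe set per gene, UCP3 at an adjusted p of 0.0403, against 0 over all genes tested. The animal scores differed by 0.45 (95% interval 0.07 to 0.83), with a two-sided exact permutation p of 0.0174 and an adjusted p of 0.244 over the 14 lists. The camera adjusted p was 0.132 without control animal 5, 0.180 without high-oleic animal 3, 0.0526 without high-oleic animal 1, 0.0557 in animals of 109.5 to 118 kg and 0.708 with live weight in the fit, where the median difference was 0.14. Without high-oleic animal 8 the median was 0.25.

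With all animals and diet alone in the fit, camera called none of the 12 other lists. The difference in animal scores was -0.16 for fibroblast and matrix genes, -0.32 for skeletal muscle, -0.09 for inflammatory cytokines and 0.25 for ribosomal proteins. It was -0.13 for oxidative phosphorylation, 0.17 for lymphocytes, 0.24 for antioxidant genes and -0.11 for de novo lipogenesis. Measured were 5 of 93 oxidative phosphorylation, 5 of 76 ribosomal, 5 of 36 antioxidant and 5 of 26 lipogenesis genes. These scores therefore do not stand for whole pathways. It was -0.04 for immediate early and heat shock genes, 0.19 for the interferon response, -0.04 for endothelium and 0.08 for macrophages. The interferon difference was 0.67 without control animal 1 and -0.16 without high-oleic animal 2, and that of skeletal muscle was 0.08 without control animal 2. The signs for endothelium, macrophages and immediate early genes also turned when single animals were left out. Others kept their sign but not their size, such as de novo lipogenesis at -0.24 to -0.00503, fibroblast and matrix genes at -0.32 to -0.05 and oxidative phosphorylation at -0.18 to -0.03. The lowest camera adjusted p of these was 0.159, for fibroblast and matrix genes. Adjusted over the list alone, PTGS2 passed among the 16 inflammatory genes at 0.0499 in the same fit per gene. That list's median difference was 0.03, against its mean of -0.09. Splits of the same animals without regard to diet called as many lists in 73 of 100 cases.

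**Figure D2:**
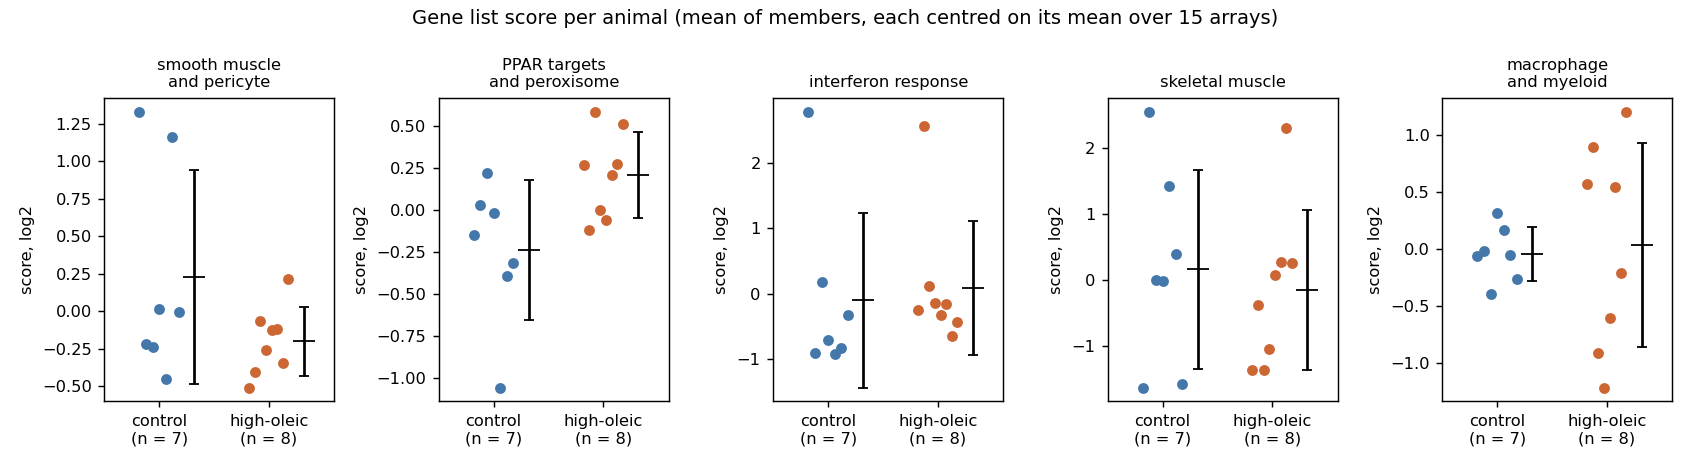
Gene list score per animal for 5 lists, in log2 units, with the group mean and SD beside the points (control, n = 7, and high-oleic, n = 8). Control animal 1 and high-oleic animal 2 had interferon scores of 2.78 and 2.56, and control animal 2 and high-oleic animal 7 had skeletal muscle scores of 2.55 and 2.31.

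Live weight at slaughter was lower on the high-oleic diet, at 109.2 ± 3.52 kg (SD, n = 8) against 117.2 ± 7.32 kg (SD, n = 7). The difference was -8.03 kg, with a two-sided exact permutation p of 0.00435 over 6435 splits. Without control animal 5, the heaviest at 133 kg, the difference was -5.40 kg with an exact p of 0.0113. Diet and live weight therefore overlapped in this series.

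At fixed diet, the slope on live weight was negative for PDK4, largely through control animal 5, and positive for ACACA. No probe set passed the test. The slope was -1.46 per 10 kg for PDK4 (SE 0.35) and 0.99 for ACACA (SE 0.28), on the log2 scale. Other genes with small p were the sulfotransferase SULT2A1 at 1.64, the interferon-induced MX2 at -1.15 and SCRG1 at -1.37. In limma, 0 of 3255 probe sets had an adjusted p under 0.05 and 124 an unadjusted p under 0.05. Without control animal 5, the slope was -0.24 for PDK4, 1.47 for ACACA, 2.85 for SULT2A1, -1.40 for MX2 and -0.96 for SCRG1. Without control animal 2, whose skeletal muscle score was the highest at 2.55, limma placed 5 probe sets past the threshold. These were 2 of TTN and 1 each of NEB and KLHL41, all rising with weight, and 1 without a gene name that fell. Control animal 5 and high-oleic animal 7, the heaviest of each diet, were still in that fit, with muscle scores of 1.43 and 2.31. TTN, on its list probe set, was 6.29 and 6.04 in them, and NEB 7.49 and 7.19. In the other animals of that fit TTN was at most 3.996 and NEB at most 5.36. The TTN and NEB calls may therefore lean on these 2 animals, and were not tested without them. Without high-oleic animal 7, limma placed 2 probe sets past the threshold, 1 of PDK4 and the same unnamed one. The fit without high-oleic animal 7 still held control animal 5. The genes past the threshold without 1 animal were named after their values were seen.

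**Figure D3:**
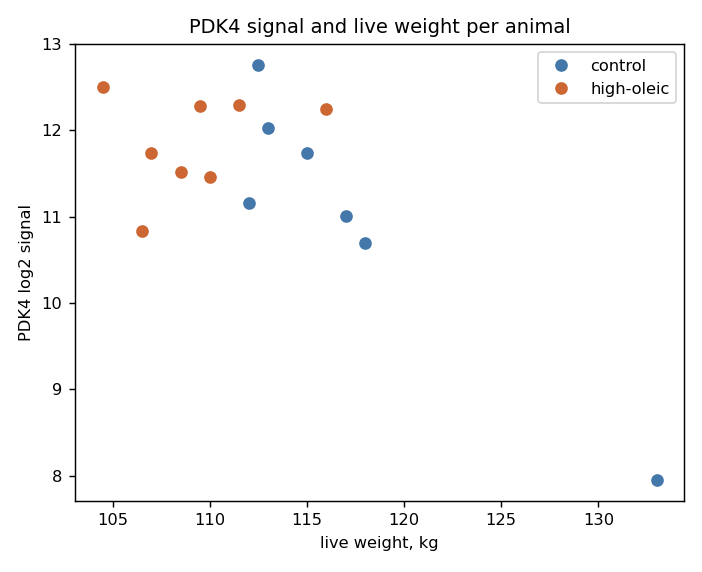
PDK4 log2 signal (vertical axis) against live weight in kg (horizontal axis), with 1 point per animal and colours for diet. The animal of 133 kg had a PDK4 signal of 7.95, below all others.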

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

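The tests of vessel tissue, skeletal muscle, array defects, leukocytes, RNA degradation, mRNA input and single arrays, and the split count at an adjusted p, were set in this form after the results were seen. Within each diet group, 112 checks for an animal far from the others gave 17 such values. Chance would give about 5.60 if the checks were independent. Several of the 17 fell on the same animal, and some genes had been named through values of that animal. The excess is therefore not a test.

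The interferon score was 2.78 in control animal 1, against a median of -0.76 in the other 6 control animals. It was 2.56 in high-oleic animal 2, against a median of -0.24 in the other 7. Control animal 1 was the highest of its group in all 19 list members and high-oleic animal 2 in 18 of 19. A local defect of either array would leave the separate control probe sets of RSAD2, an interferon-induced antiviral gene, in the range of the group. They exceeded the highest other animal of the group by at least 3.79 in control animal 1 and 3.75 in high-oleic animal 2, which argues against it. More leukocytes would raise their markers with the interferon genes. In control animal 1 the interferon score stood 3.55 above the median of the others, the macrophage score -0.03 and the lymphocyte score 0.56, short by at least 8.18 SD, which argues against more leukocytes of the kind in the other animals. In high-oleic animal 2 these were 2.80, 1.11 and 0.75, and the smaller shortfall of 1.91 SD, for macrophages, leaves them open. No biological explanation was tested, as the labels give no health record.

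The first component of expression, with 23.3% of the variance, was 48.6 in high-oleic animal 8 against a median of -12.7 in the others of its group. Over the 15 animals it correlated with the signal of transcripts spiked into the RNA (r = 0.885, permutation p = 2.0e-05, rho = 0.818, permutation p = 0.00025, r = 0.731 without the 2 animals farthest from the median). Within diets r was 0.850 among control animals (exact permutation p = 0.0119) and 0.941 among high-oleic animals (exact permutation p = 0.00161), and among control animals it was 0.537 without the 2 farthest. Along this component r was 0.779 without high-oleic animal 8 (permutation p = 0.00107). The component itself was computed with that animal included, so one array alone stays open as its source. Single probe sets also leaned on that animal. With diet in the fit, 735 followed the spiked signal at an adjusted p under 0.05, against 1 without that animal and 105 then under 0.10. Compression of bright against dim probe sets at low mRNA input stays open. Its rho of -0.081 across genes, which are not independent replicates, was -0.087 to -0.072 over animals left out, weak but in the direction it predicts, and the deposited values may have been scaled between arrays. RNA degradation stays open too, as the actin 3′ minus 5′ signal gave r = 0.363 with a 95% interval of -0.18 to 0.74 (adjusted p = 0.223 over 6 relations).

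The lower smooth muscle score on the high-oleic diet, which rested largely on control animals 1 and 6, was weighed against the makeup of the samples. As a source of the pattern, skeletal muscle carried into the fat would have to raise both scores together. They gave r = -0.247 with an upper 95% bound of 0.30 (permutation p = 0.383), which argues against that source. Less vessel tissue stays open: the smooth muscle difference exceeded the endothelial one by -0.39, with a 95% interval of -0.99 to 0.21. With live weight in the fit the difference was -0.63, not smaller, but its interval of -1.36 to 0.10 includes 0 and leaves live weight open. In that fit the list median was -0.73 and the camera adjusted p 4.85e-05 at the preset correlation, and in animals of 109.5 to 118 kg it was 0.0168. At fixed diet, camera at the preset correlation put this list lower in heavier animals (unadjusted p = 0.0254). Without control animal 5, at 133 kg, the list was higher in heavier animals (unadjusted p = 0.319). The larger difference with live weight in the fit may therefore lean on that animal, and was not tested without it. Diet itself remains untested beyond the comparison above.

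Live weight was 133 kg in control animal 5, against a median of 114 in the others of its group. In the same animal PDK4 was 7.95 against 11.45, ANGPTL4 8.57 against 10.15 and CPT1A 7.67 against 9.22, with 1 further value of 4.10 against 2.19. In high-oleic animal 8 the score was 0.50 for endothelium, 1.00 for fibroblast and matrix genes and 0.72 for immediate early and heat shock genes. In high-oleic animal 2 the oxidative phosphorylation score was -0.78 and PTGS2 was 5.002, against medians of 0.06 and 5.69. In high-oleic animal 7 the skeletal muscle score was 2.31 and PDLIM3 was 4.04, against medians of -0.37 and 3.12. HSD3B1 was 7.00 in high-oleic animal 6 against 8.65, and NCOA2 was 6.44 in control animal 7 against 5.79.

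Chance could not be excluded for the count of probe sets at an unadjusted p or for the called lists. At an unadjusted p under 0.05, 58 of 100 splits of the animals gave 128 probe sets or more, and the highest other split gave 515. Such a count may point to a structure of the samples other than diet. It is the highest of 100 splits, though, and what that split separates was not tested. At an adjusted p under 0.05 the real count was 0, which all 100 splits reach by construction, so this count tests nothing; the highest other gave 2. The 2 lists called by camera were matched or exceeded in 73 of 100 splits, with up to 6 lists in another split. With an estimated correlation no split called a list.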

How the results depend on the processing

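The spiked signal as a covariate, the samples without outlying animals and the permutation of list scores were chosen after seeing the data. The count of 0 diet probe sets held in limma under every alternative chosen in advance at an adjusted p under 0.05, and the unadjusted threshold gives 128. With the spiked signal as a covariate it was 1, CKB at -1.97 with an adjusted p of 0.00708. Elsewhere the adjusted p of CKB lay between 0.0822 and 0.9995. Counts at an unadjusted p under 0.05 were 66 in the brighter probe sets, 52 per gene and 197 with array weights, with 51.5%, 65.4% and 39.6% of them higher on the high-oleic diet, against 51.6% of the 128. With live weight in the fit 63.9% of 97 were higher.

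The 2 called lists became 0 with an estimated correlation, 0 with fry and 0 in a permutation of the animal scores. With live weight in the fit 3 were called, inflammatory, interferon and smooth muscle. In animals of 109.5 to 118 kg there were 4, fibroblast, inflammatory, macrophage and smooth muscle. With the spiked signal there were 4, both lists with fibroblast and interferon. Without control animal 1 and high-oleic animals 2 and 8 there were 5, fibroblast, interferon, macrophage, PPAR and ribosomal. Without single animals there were 1 to 4. For smooth muscle, the adjusted p was 0.502 with an estimated correlation, 0.849 with fry and 0.813 by permutation. It was 0.0786 without control animal 1 and high-oleic animal 2, 0.0819 without high-oleic animal 8 as well, and 1.46e-05 to 0.0549 without single animals. For the PPAR list these were 0.410, 0.320 and 0.244, with 0.708 with live weight, 0.0557 in the weight window and 0.00333 to 0.180 without single animals. That call was lost without control animal 5 (0.132) or high-oleic animals 1 (0.0526) or 3 (0.180). The cause was not tested.

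The animal numbers are of different animals, and they were not treated as pairs. Deviations of same-numbered animals correlated between -0.161 and 0.296, with 4 of 7 above 0.1 and 2 of 7 best with their own number. With the number as a replicate block, limma placed 0 probe sets past the threshold and 194 at an unadjusted p under 0.05, and camera called 3 lists, both lists and fibroblast. As number 8 occurs once, the block also removes high-oleic animal 8 from the difference. The labels give no processing batch, so whether the block or the spiked signal stands for one was not tested.

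Among named genes, 4 turned sign. FASN was -0.0496 with the block, -0.0730 with array weights, -0.19 with the spiked signal, -0.0474 without the 3 animals, 0.49 with live weight, 0.35 in the weight window and -0.0833 to 0.17 without single animals. ACACA was 0.70 with live weight, 0.37 in the weight window and -0.24 to 0.12 without single animals. PDK4 was -0.36 with live weight. UCP2 was -0.21 in the weight window and -0.0406 without the 3 animals. The cause was not tested. The count for live weight slopes was 0 to 5 without single animals. The live weight difference held in each, from -9.00 to -5.40 kg, and was -6.00 kg in medians. Signal over background was not analysed here, with 1 value per probe set.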

Other observations

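The test of the lipogenic genes and the list tests for live weight below were set in this form after the result was seen, as were the genes named in the next sentences. In lists too small to test, PCK1, which supplies glycerol for triglyceride synthesis in fat, was higher on the high-oleic diet by 1.47 (95% interval 0.14 to 2.79). The glycerol kinase GK was higher by 0.66, and PNPLA3, a lipase-like protein of lipid droplets, by 0.74. All 3 had unadjusted p under 0.05 and an adjusted p of 0.999 in limma. In the desaturation and elongation list SCD5 differed by -0.24 and HACD3 by -0.07.

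Skeletal muscle genes varied widely between animals of the same diet. The SD of the list score was 1.51 among control and 1.21 among high-oleic animals, against a difference of -0.32 between diets. MYL1, a fast myosin light chain, was at 10.49 in control animal 2, 9.88 in high-oleic animal 7 and 8.99 in control animal 5, and at 2.21 in control animal 1. CKM, the muscle creatine kinase, was at 9.49, 9.39, 7.66 and 2.58 in the same animals. Of 10 smooth muscle genes, 6 were highest in control animal 1 or 6 and 4 in other animals. ACTG2 was among these 4 on the probe set used for the list. On its other probe set it was at 12.65 in control animal 6 and 11.17 in control animal 1, and no other animal was above 8.46. CNN1, which encodes calponin, was at 10.24 in control animal 1 and 9.87 in control animal 6, and no other animal was above 7.56.

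A hypothesis from these data is that lipogenic genes may be higher in heavier animals on the same diet. The de novo lipogenesis score had a slope of 0.47 per 10 kg at fixed diet (95% interval 0.11 to 0.82). One heavy animal alone is argued against by a slope of 0.80 without control animal 5 (95% interval 0.15 to 1.45). FASN and ACACA are both in this list of 5 genes. Camera for live weight called 4 of 14 lists at the preset correlation and none with an estimated one, where adjusted p = 0.354 for each of the 4. Lipogenesis (adjusted p = 0.00296) and skeletal muscle (8.28e-05) were higher in heavier animals, and interferon (1.15e-08) and PPAR targets (0.0150) lower. Without control animal 5 these were 0.00202, 0.000824, 1.38e-06 and 0.900, so the PPAR call rested on that animal, and the macrophage list was called as lower in heavier animals (7.15e-07). Without control animal 1 and high-oleic animal 2, which had the highest interferon scores, the 4 were at 0.0111, 0.000690, 0.000594 and 0.00160, and the endothelial list was called as lower (0.0165). The hypothesis is not established here.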
